A study of Danio rerio with 30 samples.

How the data were processed

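Gene expression was measured in 30 samples of whole zebrafish embryos, 10 groups of 3, on 17 Agilent 2-colour arrays of 6 slides. Each sample was the red or the green channel of an array, with a dye that changed between samples of a group. On 13 arrays both channels held labelled samples. On the other 4 arrays the second channel had no label, so these 4 channels, 60 scanner columns in all, were not used. The series describes the samples as biological triplicates, but the labels do not say which came from one clutch, so p-values measure the spread between these samples.

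The spot intensities that the authors deposited are linear scanner values, read with Agilent Feature Extraction version 10.7.3.1 at 5 micron, per the file headers. The authors also deposited a value table of intensity per probe and sample, which per the series' design text was made by splitting the channels and quantile normalisation in Genedata software. Its columns all had a median of 55.1 and were on a linear scale, and its values were in rank order with the sample's own channel (rho 0.934 to 0.995 across probes, genes not being independent replicates). In all 26 samples whose array had 2 labelled channels, the table matched the sample's own channel better than the other, whose rho was at most 0.976. The other 4 samples had no second labelled channel to compare. How background was treated in that table is not given in the sources used here, so it served as an alternative.

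From the scanner files, the median signal of each spot and the median local background of the same channel were corrected with normexp (offset 50) in limma 3.58.1. The design named mean signals, but the files hold median signals, and these were used. All channels in use were then taken to log2 and quantile normalised, and the 2 spots of each probe averaged. The 1417 control spots were left out after background correction, as were spots flagged as non-uniform or as outliers among replicate spots, which left 0.52% of values missing. Of 21495 probes, 12951 were well above background in all 3 samples of at least 1 group and were kept, and 5230 were so in all 30 samples. Probes carry accessions, which were named through a table of RefSeq genes of assembly GRCz12tu, used for names only. It named 9583 probes (44.6%) of 7329 genes, and the rest keep the files' identifiers. Where a gene had several probes, as 1859 named genes did, the brightest on average was used. Among the results of genes named in the text that have other kept probes, 1 of 58 had a probe of opposite sign. Some named genes were well above background in only part of a group's 3 samples. In the dimmer group of a comparison this was 1 sample for eve1, krt17 and krt99 (uninjected genotypes), zic2b and atf3 (FoxD3-injected genotypes), casq1b, ehd2b and bmp2a (Klf4 in mutants), krt97 (FoxD3 in wild type), slc2a3a, sox19a and tbxta (Nanog-like) and apoeb, grem1a and hbba2 (cycloheximide). It was 2 samples for blf and emx3 (uninjected genotypes), dcaf13 and cdx4 (FoxD3-injected genotypes), klf17 and sox2 (Klf4 in wild type), gata6 (Klf4 in mutants), fgf8a and dazl (FoxD3 in wild type), gata5 (FoxD3 in mutants), mapk12b (FoxD3 under cycloheximide), krt5 (Nanog-like) and ccnd1, noto, tbxta and tfap2a (cycloheximide). gata5 was so in 1 wild type sample with FoxD3, and casq1b, ehd2b and gata6 in 2 cycloheximide controls. klf4, nanog and bmp2b were not matched to a probe. This left 10817 genes tested, 5781 of them named.

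Before averaging, samples of a group were compared. Klf4 samples 1 and 3 under cycloheximide differed by less than the noise between spots (0.05 against 0.058, with 0 probes over 2-fold apart), and were averaged and counted as 1 sample, so 29 samples entered the fit. One limma model held all groups, the dye as a covariate and the array as a random block (consensus correlation 0.547), with eBayes with trend and robust (prior df 6.9, residual df 18). P-values were adjusted by Benjamini and Hochberg within each comparison, and genes with adjusted p below 0.05 are called. Replicate numbers paired the samples, by the correlation of their deviations from group means, where same-numbered samples shared an array: FoxD3-injected mutants and wild type (0.49 to 0.72), Klf4 in wild type (0.73 to 0.81) and Klf4 in mutants (0.54 to 0.56). They did not for Klf4 under cycloheximide (-0.42 to 0.14), whose pairs also shared arrays, nor for the other comparisons.

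The comparisons were mutant against wild type, uninjected and with FoxD3; each injection against uninjected embryos of the same genotype and drug; cycloheximide against none in mutants; and 4 interactions. The genes named were fixed by a rule written before the data were examined. It took the mutated and injected genes, then per comparison the 10 largest rises and the 10 largest falls (5 for interactions) among called genes of at least 2-fold with all samples of one group beyond all of the other, leaving out names that are only accessions. Chance gives such non-overlap in 10% of genes with 3 samples against 3. It also took up to 4 members with the lowest adjusted p of each gene list with a call. The text names some of these, and results of certain genes are withheld and not reported here.

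The 19 gene lists were also fixed before: enveloping layer and periderm, FGF pathway, Krueppel-like factors, SoxB1 and neuroectoderm, yolk syncytial layer, cell cycle and replication, dorsal organizer, first zygotic genes, germ plasm and primordial germ cells, heat shock and unfolded protein, immediate early genes, interferon response, later tissue markers, maternal oocyte transcripts, mesendoderm and Nodal, non-neural ectoderm and BMP, p53 targets, ribosomal proteins and ribosome biogenesis. Some genes stand in more than 1 list. Each was tested with camera on the moderated statistics, with a preset correlation of 0.01, and again with an estimated one. fry, with the array block, tests whether a list's genes move one way and does not compare them with other genes. Median, mean and test direction differed in sign in 36 of 266 list results, 0 of them among the calls. Overlaps of called genes were tested with Fisher's exact test, two-sided, and adjusted over 22 overlaps of the Klf4 comparisons and, separately, over 8 of the genotype comparisons.

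The pipeline was tested on simulated data with 200 of 10817 genes changed. Of genes changed by log2 values of 0.5, 1 and 2, it recovered 29.9, 83.6 and 100% for Klf4 in mutants, 14.9, 65.7 and 98.5% for FoxD3 in mutants, 25.4, 74.6 and 98.5% for Klf4 under cycloheximide and 10.4, 56.7 and 95.5% for FoxD3 under cycloheximide. False calls were 4.1, 4, 7 and 7.7% of all calls, and 0 of 18 unchanged lists were called in each.

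Alternatives fixed before the data were examined were Agilent's processed signals, a normexp offset of 16, scaling each channel to its 75th percentile, loess within and Aquantile between arrays, the deposited value table, other filters on dim probes, no array block, the replicate number as a block, slide as a random or fixed block, no dye covariate, only the groups of a comparison, the mean of a gene's probes, eBayes with neither trend nor robust, and each sample left out. Scaling to the 75th percentile moved the median of all genes to -1.09 for cycloheximide, 0.36 for Nanog-like, 0.3 for FoxD3 in mutants, 0.25 for FoxD3 in wild type, -0.19 for uninjected mutants, -0.16 for Klf4 in mutants and 0.14 for FoxD3 under cycloheximide, so counts of higher and lower genes are relative to that choice. For interactions it was 0.18 and 0.12 for FoxD3 by genotype and Klf4 by drug, and -0.13 for Klf4 by genotype. Software was R 4.3.3, statmod 1.5.0, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.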

Results

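Transcript levels were measured in whole zebrafish embryos frozen at 4.7 hours post fertilisation, in the late blastula, on 2-colour Agilent oligonucleotide arrays. The embryos were wild type or maternal-zygotic spg mutants (MZspg), in which neither the maternal nor the zygotic copies of pou5f3, the zebrafish relative of the mammalian pluripotency gene Oct4, make a working protein. They were left uninjected or were injected with 50 to 100 pg of mRNA for a single transcription factor: Klf4 (a Krueppel-like zinc finger protein), FoxD3 (a forkhead protein) or Nanog-like (a homeodomain protein). No group received a control mRNA, so effects of injection itself cannot be told apart from those of a factor. Some MZspg embryos were also kept in 15 µg/ml cycloheximide, a blocker of protein synthesis, from 1.5 to 4.7 hours. The 30 samples formed 10 groups of 3, each sample holding RNA of 60 to 100 embryos, and the series describes them as biological triplicates. The comparisons ask which transcripts depend on Pou5f3, which respond to each injected factor with and without Pou5f3, and which of these responses remain when translation is blocked. The factors were given as mRNA, so the drug may also have limited how much of their protein was made, which was not measured here.

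The samples lay on 17 arrays of 6 slides. On slides 1 to 3, which hold all samples without cycloheximide, the median spot signal of a sample was 31.5 to 57 and 37.8 to 55.6% of spots were well above background. On slides 4 to 6, which hold the cycloheximide samples, these values were 106 to 243 and at least 52.1%. No spot was saturated, and the number of arrays limits the precision of every value. Of 10817 genes tested, 5781 (53.4%) had a name. Differences are given as log2 values ± SE with limma's adjusted p, with n = 3 per group unless another n is given, since spots left out took some values away, and n = 2 for Klf4 under cycloheximide after a pair of samples was averaged. Where no sample of the dimmer group had both spots of the probe well above background, the ratio is given as "at least N-fold", from the bright group's mean against the higher of the dim probe and the floor of detection. Differences between responses that involve such a group are given with their direction and adjusted p, without a size.

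The pou5f3 transcript itself was bright in both genotypes: 13.71 ± 0.23 in uninjected mutants and 15.33 ± 0.66 in uninjected wild type (log2 signal, SD, n = 3). The difference of -1.62 ± 0.55 passed the test (adjusted p = 0.0457) and that of -1.03 ± 0.38 between FoxD3-injected embryos did not (adjusted p = 0.0514). Whether the probe lies in the part that the mutation changes is not given in the sources used here, so it does not check the labels. klf17, a Krueppel-like gene of the first zygotic transcripts, was at least 1.77-fold lower in uninjected mutants and at least 1.67-fold lower in FoxD3-injected mutants than in the wild type, from 1 of its 2 probes. The other klf17 probe was not well above background in any full group. With Klf4 in wild type klf17 was lower by -0.58 ± 0.08 at its brighter probe (adjusted p = 1.32e-05) and pou5f3 by -1.24 ± 0.38 (adjusted p = 0.0394), which did not pass without wild type control 1 (-0.9, adjusted p = 0.358). pou5f3 did not pass with Klf4 in mutants (-1.05 ± 0.38, adjusted p = 0.0696). Both foxd3 probes were not well above background in any of the 30 samples, the FoxD3-injected ones included. They may lie outside the injected mRNA and do not check the injections. Probes of klf4 and nanog were not named here.

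**Figure D1:**
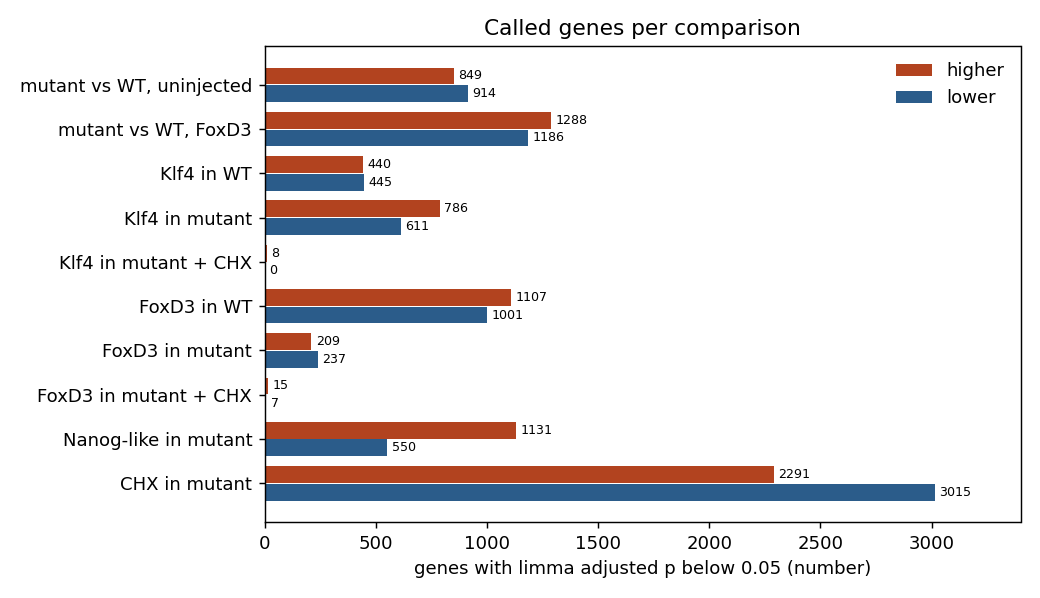
Number of genes (x axis) with limma adjusted p below 0.05 in each of the 10 comparisons (y axis), red for higher and blue for lower in the first-named group. Cycloheximide gave the most calls (2291 higher, 3015 lower), and the comparisons under cycloheximide the fewest (8 and 22 in all). WT, wild type; CHX, cycloheximide.

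Uninjected mutants had lower levels of enveloping layer and first zygotic transcripts than uninjected wild type embryos. The enveloping layer is the outer epithelium of the embryo, and its keratins krt97 (-3.38 ± 0.25, adjusted p = 2.07e-10), krt5 (-3.16 ± 0.36), krt17 (-2.7 ± 0.18) and krt99 (-3.96 ± 0.25) were lower, as was snai2, a zinc finger repressor (-4.22 ± 0.28, n = 2 in each group). The transcription factors sox2 (-2.1 ± 0.3) and sox11a (-3.31 ± 0.34) were lower too. The caudal-type gene cdx4 was at least 7.52-fold and dcaf13, a ribosome assembly factor, at least 38.1-fold lower. Higher in the mutants were the forebrain gene emx3 (2.75 ± 0.28) and nr2f1a, an orphan nuclear receptor (at least 6.67-fold). The ventral homeobox gene ved also passed (3.01 ± 0.65, adjusted p = 0.00225), at 11.92 ± 0.48 in mutants (n = 3), but its 2 wild type values lay far apart (8.88 ± 2.48, n = 2). In all, 1763 genes passed, 849 higher and 914 lower, of which 845 differed at least 2-fold. The count was 542 when only these groups were fitted and 487 when scaled to the 75th percentile.

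Of 15 measured enveloping layer genes, 12 were lower and 0 higher (13 lower adjusted over the list alone, camera adjusted p = 2.58e-21, and adjusted p = 3.27e-05 with an estimated correlation). Of 24 first zygotic genes, the earliest transcripts of the embryo's own genome, 11 were lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 1.16e-07), among them blf (-3.08 ± 0.53), znfl1 (at least 2.53-fold) and the T-box gene tbx16 (at least 2.88-fold). Lower in the same way were 6 of 12 FGF pathway genes such as dusp6 (-1.61 ± 0.31; 6 adjusted over the list alone, adjusted p = 0.00785). So were 3 of 10 Krueppel-like genes, with klf2b at -3.2 ± 0.39 and 1 higher, klf6a at 0.76 ± 0.26 (the same counts adjusted over the list alone, adjusted p = 0.0217). Of 21 mesendoderm genes 7 were lower, such as foxa2 (-1.41 ± 0.28) and gata6 (-1.21 ± 0.28; 10 lower and 1 higher adjusted over the list alone, adjusted p = 0.00109). Neuroectoderm genes gave 8 lower and 3 higher of 25 (the same adjusted over the list alone, adjusted p = 0.00247, and adjusted p = 0.0505 with an estimated correlation). The BMP and non-neural ectoderm list gave 5 lower, such as eve1 (-2.16 ± 0.21), and 1 higher of 21 (6 and 1 adjusted over the list alone, adjusted p = 0.00367, and adjusted p = 0.11 with an estimated correlation). The dorsal organizer list gave 4 lower of 13, such as gsc (-1.11 ± 0.27) and chrd (-1.59 ± 0.4; 4 adjusted over the list alone, adjusted p = 0.0489, and adjusted p = 0.394 with an estimated correlation). Of 21 maternal oocyte transcripts 6 were higher, such as the kinase mos (1.89 ± 0.43) and the claudin cldng (1.36 ± 0.27), and 1 lower (6 and 2 adjusted over the list alone, adjusted p = 0.0451, and adjusted p = 0.11 with an estimated correlation). Each of these groups lay on its own slide, so genotype and slide cannot be told apart here.

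The same genotype comparison between FoxD3-injected embryos came from both channels of the same 3 arrays. dcaf13 (-4.69 ± 0.11, adjusted p = 2.88e-21), zic2b (-2.3 ± 0.31), cdx4 (-2.1 ± 0.18), klf2b (-1.32 ± 0.27) and foxb1b (at least 5.2-fold) were lower in the mutants. Immediate early genes, which respond fast to signals and stress, were higher: 17 of 27 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 1.13e-06, and adjusted p = 0.000775 with an estimated correlation), with jun at 1.85 ± 0.2, junbb at 1.74 ± 0.14, the phosphatase dusp5 at 1.53 ± 0.17 and atf3 at 1.29 ± 0.15. ved was lower in the mutants (-1.87 ± 0.4). The enveloping layer list gave 2 higher and 1 lower of 15 (1 and 1 adjusted over the list alone, adjusted p = 0.964). In all, 2474 genes passed, 1288 higher and 1186 lower, against 1491 when only these groups were fitted and 689 when scaled to the 75th percentile.

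The neuroectoderm list gave 9 lower and 3 higher of 25 (the same adjusted over the list alone, adjusted p = 0.00243, and adjusted p = 0.0866 with an estimated correlation), and the first zygotic list 10 lower and 1 higher of 24 (10 and 4 adjusted over the list alone, adjusted p = 0.00215, and adjusted p = 0.0866 with an estimated correlation). Ribosomal protein genes gave 14 higher of 63, such as rpl29 (1.61 ± 0.23) and rps2 (1.41 ± 0.25; 14 adjusted over the list alone, adjusted p = 0.00403, and adjusted p = 0.672 with an estimated correlation). The uninjected and the FoxD3-injected genotype comparisons share no samples. They had 393 higher genes in common, where independent lists of these sizes give 101 (Fisher's exact test, adjusted p = 1.88e-154), and 408 lower genes, where such lists give 100 (adjusted p = 5.7e-169). Their r across genes was 0.51; genes are not independent replicates.

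**Figure D2:**
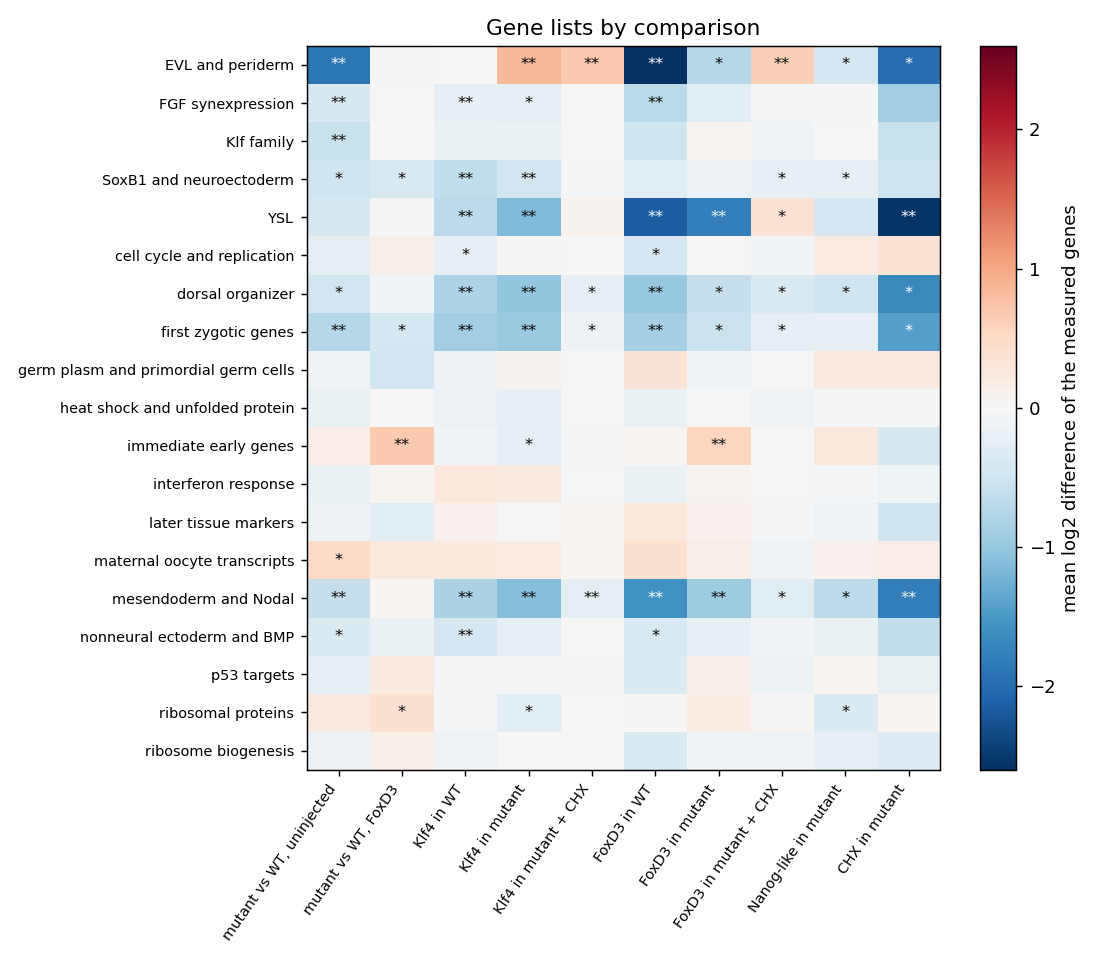
Mean log2 difference (colour) of the measured genes of the 19 gene lists (y axis) in the 10 comparisons (x axis). Asterisks mark camera adjusted p below 0.05, 2 asterisks where this held also with an estimated correlation. The enveloping layer list ran from -2.58 for FoxD3 in wild type to 0.85 for Klf4 in mutants. EVL, enveloping layer; YSL, yolk syncytial layer; WT, wild type; CHX, cycloheximide.

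Klf4 in wild type embryos raised genes of varied function and lowered first zygotic, mesendoderm and neuroectoderm genes. The homeobox gene shox2 rose by 4.52 ± 0.16 (adjusted p = 1.44e-16), the membrane remodelling gene ehd2b by 3.53 ± 0.13, the BMP antagonist nog3 by 2.99 ± 0.18, the fast muscle troponin tnni2a.3 by 2.68 ± 0.12 and the proteoglycan decorin, dcn, by 2.76 ± 0.16. The calcium store gene casq1b of muscle rose at least 10.1-fold, the claudin cldn15a at least 9.6-fold and icn, a calcium-binding gene of the enveloping layer, at least 5.7-fold. The SoxB1 genes sox3 (-2.47 ± 0.21, adjusted p = 1.7e-09) and sox2 (-2.05 ± 0.21), the organizer gene gsc (-2.22 ± 0.2, n = 2 with Klf4), the homeobox repressor vox (-1.87 ± 0.25) and the notochord gene tbxta (-1.68 ± 0.27) were lower. In all, 885 genes passed, 440 higher and 445 lower, 240 of them at least 2-fold.

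First zygotic genes fell together: 13 of 24 were lower and 0 higher (17 lower adjusted over the list alone, camera adjusted p = 2e-19). Mesendoderm genes gave 13 lower of 21 (17 lower and 1 higher adjusted over the list alone, adjusted p = 2.71e-12), and neuroectoderm genes 10 lower and 1 higher of 25 (11 and 3, adjusted p = 2.73e-11). Organizer genes gave 6 lower of 13 (11, adjusted p = 4.5e-09), BMP genes 7 lower and 1 higher, bmp2a at least 2.94-fold, of 21 (10 and 1, adjusted p = 3.86e-06), yolk syncytial layer genes 2 lower of 7 (6, adjusted p = 0.00102) and FGF genes 5 lower and 1 higher of 12 (6 and 1, adjusted p = 0.00445). The bracketed counts are those adjusted over the list alone. These 7 calls held with an estimated correlation. The cell cycle list, with 5 of 25 lower such as the replication gene mcm6 (-1.36 ± 0.17), did not (5 adjusted over the list alone, adjusted p = 0.0229, and adjusted p = 0.166 with an estimated correlation). Enveloping layer genes went both ways, with a median of -0.2, a mean of 0.02 and a downward test direction: icn and krt97 (1.33 ± 0.17) were among 3 higher, and krt17 (-1.48 ± 0.12) and cyt1 (-1.11 ± 0.15) among 4 lower of 15 (the same counts adjusted over the list alone, adjusted p = 0.958). The later tissue list, which holds other muscle genes, had 0 of 9 called by limma (0 adjusted over the list alone, adjusted p = 0.941). The interferon list gave irf1b (2.46 ± 0.19) and stat1b (at least 2.74-fold) as 2 higher and 2 lower of 9 (3 and 3 adjusted over the list alone, adjusted p = 0.107). The count of called genes was 526 without wild type control 2, 520 without wild type Klf4 sample 2, 2396 when only these groups were fitted and 230 when scaled to the 75th percentile.

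In MZspg embryos Klf4 raised keratins that were lower in uninjected mutants, and other genes, several of which also rose in wild type. Both comparisons use the same mutant controls, so chance values there count in both. Of all genes lower in uninjected mutants, 73 were higher with Klf4, where independent lists give 66.4 (Fisher's exact test, adjusted p = 0.607). Those also lower with Klf4 numbered 135, where such lists give 51.6 (adjusted p = 4.72e-26). krt5 rose by 3.5 ± 0.25 (adjusted p = 6.57e-11) to 12.86 ± 0.08, against 12.51 ± 0.57 in uninjected wild type (log2 signal, SD, n = 3), and krt97 by 3.15 ± 0.17 (adjusted p = 3.18e-13). The homeobox gene dlx3b of the non-neural ectoderm rose by 2.39 ± 0.15, the transporter gene slc6a1b by 3.58 ± 0.23, the interferon regulator irf1b by 3.05 ± 0.19, casq1b by 3.52 ± 0.13, ehd2b by 3.52 ± 0.13 and shox2 by 3.11 ± 0.16. Lower were sox3 (-2.32 ± 0.21), gsc (-2.22 ± 0.19), tbxta (-2.05 ± 0.27), gata6, an endoderm factor (-1.86 ± 0.19), the apolipoprotein gene apoeb of the yolk syncytial layer (-2.5 ± 0.39) and ved (-2.19 ± 0.4). In all, 1397 genes passed, 786 higher and 611 lower, 348 of them at least 2-fold. Of 15 enveloping layer genes, 7 were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 1.24e-08, and adjusted p = 0.0115 with an estimated correlation).

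Mesendoderm genes gave 15 lower of 21 (adjusted p = 9.23e-17), first zygotic genes 16 lower of 24 (adjusted p = 5.89e-13), organizer genes 8 lower of 13 (adjusted p = 4.71e-11), yolk syncytial layer genes 5 lower of 7 (adjusted p = 5.71e-06) and neuroectoderm genes 11 lower and 2 higher of 25 (adjusted p = 8.99e-06). These calls held with an estimated correlation. Adjusted over the list alone, these lists had 15, 17, 11, 5 and 13 lower, and the neuroectoderm list 3 higher. FGF genes gave 5 lower and 1 higher of 12 (8 and 2 adjusted over the list alone, adjusted p = 0.0391, and adjusted p = 0.0525 with an estimated correlation), and immediate early genes 8 lower, with dusp5 at -1.17 ± 0.17, and 1 higher of 27 (10 and 2 adjusted over the list alone, adjusted p = 0.0132, and adjusted p = 0.0854 with an estimated correlation). Ribosomal protein genes gave 4 lower of 63 (0 adjusted over the list alone, adjusted p = 0.000217, and adjusted p = 0.296 with an estimated correlation). BMP and non-neural ectoderm genes went both ways, with 6 higher, dlx3b and bmp2a (1.73 ± 0.11) among them, and 7 lower, such as tfap2a (-1.63 ± 0.2), of 21 (6 and 10 adjusted over the list alone, adjusted p = 0.759). The Krueppel-like list had a median of 0.08, a mean of -0.18 and an upward test direction (1 higher and 2 lower of 10, the same adjusted over the list alone, adjusted p = 0.934). The count of called genes was 873 without mutant Klf4 sample 2, 808 without sample 3 and 303 when only these groups were fitted.

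The wild type and mutant Klf4 comparisons share no samples. They had 200 higher genes in common, where independent lists give 32 (Fisher's exact test, adjusted p = 2.15e-114), and 213 lower genes, where such lists give 25.1 (adjusted p = 3.78e-154). Among these were casq1b, shox2 and nog3, higher in both, and gsc, sox3 and tbxta, lower in both, and r across genes was 0.51. The Klf4 comparison in mutants was also set against the FoxD3-injected genotypes, with which it shares no samples. Of the genes lower in those mutants 94 were higher with Klf4, where independent lists give 86.2 (Fisher's exact test, adjusted p = 0.58). Genes higher in those mutants and lower with Klf4 numbered 147, where independent lists give 72.8 (adjusted p = 3.88e-17). The overlaps in the same direction also passed, with 127 genes higher in both, where independent lists give 93.6 (adjusted p = 0.000532), and 105 lower in both, where they give 67 (adjusted p = 6e-06).

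**Figure D3:**
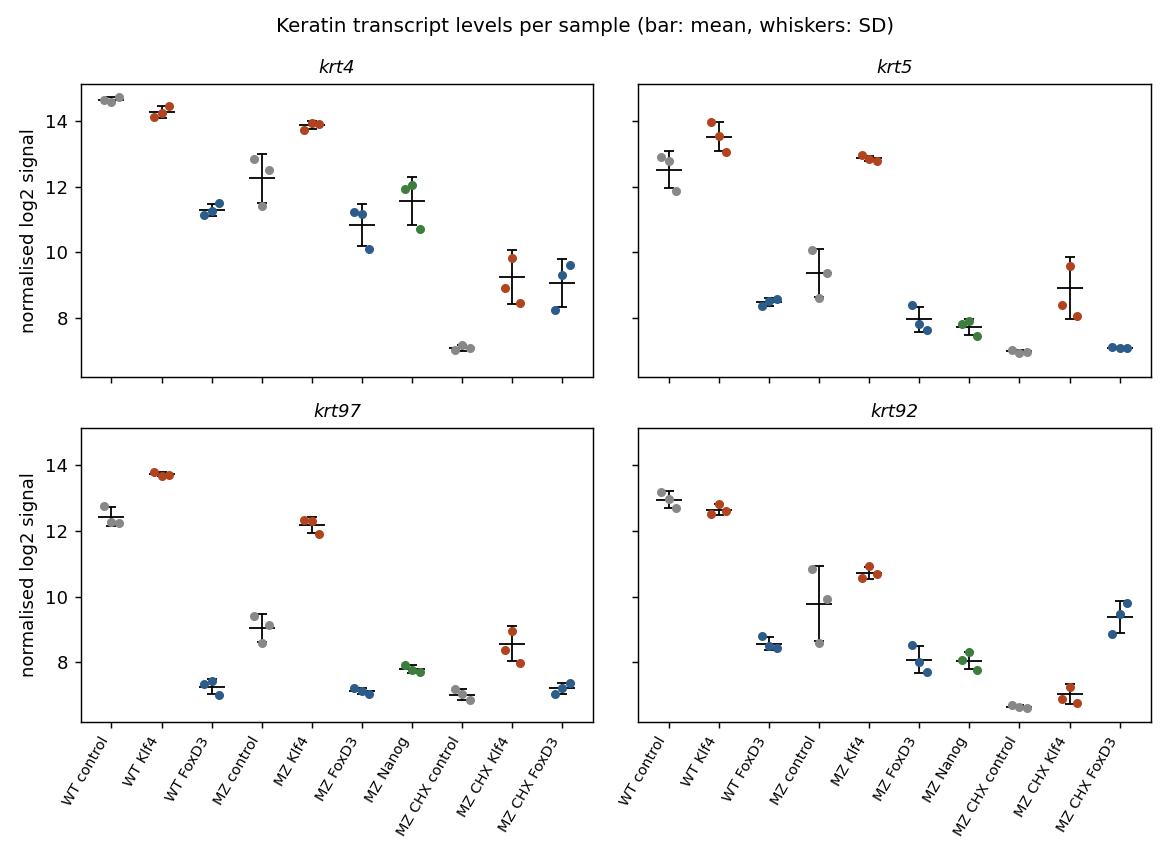
Normalised log2 signal (y axis) of krt4, krt5, krt97 and krt92 in each of the 30 samples (points) of the 10 groups (x axis), with the mean and SD of each group (the pair of near-equal Klf4 samples under cycloheximide counted as 1). krt97 lay at 12.43 ± 0.29 in wild type controls, 9.04 ± 0.42 in mutant controls, 12.18 ± 0.24 in mutants with Klf4 and 7.13 ± 0.09 in mutants with FoxD3. WT, wild type; MZ, MZspg; CHX, cycloheximide.

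Under cycloheximide, Klf4 raised 3 named genes in mutants, all keratins of the enveloping layer. krt4 rose by 2.37 ± 0.38 (adjusted p = 0.0024), krt5 by 2.15 ± 0.33 (adjusted p = 0.00179) and krt97 by 1.69 ± 0.23 (adjusted p = 0.000332). Their levels stayed low: krt4 reached 9.24 ± 0.81 (log2 signal, SD, n = 2 after averaging a pair) against 7.08 ± 0.09 in the cycloheximide controls and 13.87 ± 0.12 with Klf4 alone (n = 3). In all 8 genes passed, 8 higher and 0 lower by limma, with 35 at an unadjusted p below 0.05, and all 8 were also higher with Klf4 without cycloheximide, where independent lists give 0.581 (Fisher's exact test, adjusted p = 3.31e-09). The 5 without a name include the 2 probes that rose most by adjusted p, and if these read the injected RNA, which is not known, they would be higher in both by construction. The enveloping layer list had 3 higher of 15 (5 adjusted over the list alone, camera adjusted p = 1.9e-38, and adjusted p = 1.99e-09 with an estimated correlation). The mesendoderm list shifted down with 0 members called by limma either over all genes or adjusted over the list alone (adjusted p = 3.42e-05, and adjusted p = 0.019 with an estimated correlation), and the organizer (adjusted p = 0.000706, and adjusted p = 0.117 with an estimated correlation) and first zygotic lists (adjusted p = 0.000756, and adjusted p = 0.0606 with an estimated correlation) likewise had 0 called. The count was 15 with the averaged pair counted as 2 samples, 2 without cycloheximide control 2 and 4 without Klf4 sample 2. It was also 4 with no array block, 2 when only these groups were fitted and 15 when scaled to the 75th percentile. The array block used the same consensus correlation for all comparisons, though replicate numbers did not pair the samples of this comparison.

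FoxD3 in wild type embryos lowered enveloping layer, yolk syncytial layer, mesendoderm and organizer transcripts together. krt97 (-5.17 ± 0.25, adjusted p = 3.08e-13), krt92 (-4.39 ± 0.38) and krt5 (-4.03 ± 0.36) were lower, and krt99 was at least 15.6-fold lower. The yolk syncytial layer genes afp4 (-5.23 ± 0.68) and apoeb (-3.31 ± 0.56), the organizer genes gsc (-3.07 ± 0.27) and chrd (-3.02 ± 0.4), the growth factor gene fgf8a (-3.75 ± 0.42), gata6 (at least 9.54-fold) and sox2 (at least 4.64-fold) were lower. Higher were the oocyte transcripts mos (2.31 ± 0.43) and cldng (2.44 ± 0.27) and the muscle gene klhl41b (at least 9.27-fold). The list of maternal oocyte transcripts did not pass (5 higher and 2 lower of 21, the same adjusted over the list alone, adjusted p = 0.101). In all, 2108 genes passed, 1107 higher and 1001 lower, 1038 of them at least 2-fold.

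Of 15 enveloping layer genes 12 were lower and 0 higher (12 adjusted over the list alone, camera adjusted p = 6.07e-38). Mesendoderm genes gave 13 lower of 21 (14, adjusted p = 1.52e-17), yolk syncytial layer genes 6 lower of 7 (7, adjusted p = 8.07e-08), first zygotic genes 13 lower and 3 higher of 24 (14 and 3, adjusted p = 6.69e-06), FGF genes 6 lower and 1 higher of 12 (6 and 2, adjusted p = 4.75e-05) and organizer genes 7 lower of 13 (7, adjusted p = 5.98e-05). Counts adjusted over the list alone are in brackets, and these calls held with an estimated correlation. The BMP list gave 7 lower and 2 higher of 21 (8 and 2 adjusted over the list alone, adjusted p = 0.000782, and adjusted p = 0.0767 with an estimated correlation), and the cell cycle list 8 lower, such as ccna2 (-2.13 ± 0.33), and 1 higher of 25 (10 and 2 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.167 with an estimated correlation). Germ plasm genes gave 2 higher of 12, nanos3 (1.21 ± 0.4) and dazl (0.84 ± 0.24; 3 adjusted over the list alone, adjusted p = 0.41). Each of these groups lay on its own slide, so slide and injection cannot be told apart. Scaled to the 75th percentile, 237 genes passed, 100 higher and 137 lower.

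In MZspg embryos FoxD3 again lowered mesendoderm and yolk syncytial layer genes. gsc (-2.08 ± 0.27, adjusted p = 6.54e-05), gata5 (-2.06 ± 0.38), fgf8a (-2.77 ± 0.42), apoeb (-3.07 ± 0.57) and foxd5, a forkhead gene (-2.57 ± 0.34, n = 2 for the controls), were lower. The keratin krt4 did not pass (-1.33 ± 0.41, adjusted p = 0.0687). krt97 was at least 3.48-fold, gata6 at least 3.47-fold, the yolk syncytial layer regulator mxtx1 at least 3.85-fold (n = 2 for the controls) and the zinc finger gene drl at least 7.01-fold lower. Higher were sox4b (2.21 ± 0.46), osgn1, an oxidative stress gene (at least 2.99-fold, adjusted p = 9.76e-07), cdx4 (at least 1.74-fold), klf2b (1.5 ± 0.39) and the immediate early genes gadd45ba (1.35 ± 0.31) and myca (1.22 ± 0.22). In all, 446 genes passed, 209 higher and 237 lower, 239 of them at least 2-fold.

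Mesendoderm genes gave 11 lower of 21 (13 lower and 2 higher adjusted over the list alone, camera adjusted p = 1.45e-11) and yolk syncytial layer genes 5 lower of 7 (7, adjusted p = 5.46e-12). Immediate early genes gave 4 higher and 1 lower of 27 (12 and 1 adjusted over the list alone, adjusted p = 2.87e-08), and these 3 calls held with an estimated correlation. Enveloping layer genes gave 5 lower of 15 (8 adjusted over the list alone, adjusted p = 2.41e-06, and adjusted p = 0.0671 with an estimated correlation). Organizer genes gave 4 lower of 13 (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.124 with an estimated correlation) and first zygotic genes 6 lower of 24 (9 lower and 4 higher adjusted over the list alone, adjusted p = 0.00409, and adjusted p = 0.104 with an estimated correlation). The groups lay on slides 2 and 3; with slide as a fixed block, which rests on the Nanog-like samples of both slides, 680 genes passed, 108 of the 446 among them. The count was 9 when only these groups were fitted, 813 without mutant control 3, 760 without FoxD3 sample 1, 238 without sample 2 and 240 without sample 3. The 209 higher and 237 lower became 133 and 292 from Agilent's processed signals, 96 and 216 in the deposited value table and 3 and 17 scaled to the 75th percentile.

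Under cycloheximide the keratin krt92, lower with FoxD3 in mutants without the drug, was higher, as were other keratins. krt92 rose at least 6.29-fold (adjusted p = 0.000743), krt17 at least 2.07-fold, cyt1 at least 2.17-fold and krt4 by 2.02 ± 0.41 (adjusted p = 0.0278), and the kinase gene mapk12b by 1.65 ± 0.34. The neural homeobox gene irx7 (-2.23 ± 0.45, adjusted p = 0.0296) and the Nodal antagonist lft2 (-1.68 ± 0.36) were lower. irx7 lay at 9.52 in cycloheximide control 1, near the FoxD3 samples (9.15 to 9.32), so its difference rests on controls 2 and 3 (12.32 and 12.65). lft2 likewise lay at 8.37 in control 1, and at 9.69 and 9.92 in controls 2 and 3. In all 22 genes passed, 15 higher and 7 lower. Of 15 enveloping layer genes 4 were higher (4 adjusted over the list alone, camera adjusted p = 1.38e-17, and adjusted p = 0.000274 with an estimated correlation). Of the other lists below the threshold none held. The organizer list had 0 called of 13 by limma (1 lower adjusted over the list alone, adjusted p = 0.000267, and adjusted p = 0.0942 with an estimated correlation). The mesendoderm list had 1 lower of 21 (1 adjusted over the list alone, adjusted p = 0.00158, and adjusted p = 0.0942 with an estimated correlation). The neuroectoderm list had 1 lower of 25 (1 adjusted over the list alone, adjusted p = 0.00669), and its mean of -0.21 was 0.02 scaled to the 75th percentile. The first zygotic list had 0 called of 24 by limma (0 adjusted over the list alone, adjusted p = 0.00476). The yolk syncytial layer list had 0 called of 7 by limma (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0156). For these last 3 lists adjusted p = 0.0946 with an estimated correlation. The FoxD3 samples lay on slides 4, 5 and 6 and the controls on slide 4: with slide as a fixed block 1 gene passed, and with the slide 4 FoxD3 sample alone, or with only these groups fitted, 0 passed by limma. Scaled to the 75th percentile 51 passed. The count was 157 without cycloheximide control 1, 9 without control 2, 12 without control 3, 6 without FoxD3 sample 2 and 3 without sample 3.

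Nanog-like in MZspg embryos lowered some embryonic regulators and raised other genes. The notochord genes noto (-3.14 ± 0.5, adjusted p = 0.000323) and tbxta (-2.03 ± 0.43), the Sox genes sox11b (-2.51 ± 0.41) and sox19a (-2.19 ± 0.59) and krt5 (-1.68 ± 0.39) were lower. The glucose transporter gene slc2a3a (2.92 ± 0.29, adjusted p = 1.66e-06), igfbp1a, a binder of insulin-like growth factors (2.32 ± 0.3), the maternal transcript btg4 (2.54 ± 0.39) and the cytokine feedback gene socs3b (1.75 ± 0.27) were higher. In all, 1681 genes passed, 1131 higher and 550 lower, 909 of them at least 2-fold, but 13 genes when only these groups were fitted.

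The lists that passed fell, and none held with an estimated correlation. Mesendoderm genes gave 6 lower of 21 (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.186 with an estimated correlation). Ribosomal protein genes gave 9 lower of 63 (adjusted p = 0.000918), enveloping layer genes 3 of 15 (adjusted p = 0.0141) and organizer genes 3 of 13 (adjusted p = 0.0346). Neuroectoderm genes gave 6 lower and 2 higher of 25 (adjusted p = 0.0291). These 4 counts were the same adjusted over the list alone, and in each adjusted p = 0.367 with an estimated correlation. The p53 target list gave 3 higher of 13 (5 adjusted over the list alone, adjusted p = 0.739), and the interferon list 0 called of 9 by limma (0 adjusted over the list alone, adjusted p = 0.573). Samples 1 and 2 were both channels of 1 array on slide 2, and sample 3 lay on slide 3 with the controls. Samples 1 and 2 differed from each other at 4 probes over 2-fold, and from sample 3 at 932 and 871. Their difference exceeded the noise between spots (0.146 against 0.08), and they were counted as 2 samples. Whether they hold 1 RNA is not known, so n = 3 may overstate the replication here. The count was 291 with slide as a fixed block (214 of the 1681 among them), 370 with sample 3 alone, 1032 without sample 2 and 2880 without sample 3. The split of 1131 higher and 550 lower became 23 and 194 scaled to the 75th percentile and 207 and 374 in the deposited value table.

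Cycloheximide in uninjected mutants gave more called genes than any other comparison. Among the lower genes were apoeb (-5.52 ± 0.56), krt4 (-5.22 ± 0.41, adjusted p = 2.71e-10), gsc (-4.4 ± 0.27), the cyclin gene ccnd1 (-4.08 ± 0.32), noto (-3.94 ± 0.46), tfap2a (-3.63 ± 0.29), sox3 (-3.52 ± 0.3) and tbxta (-3.24 ± 0.39). Higher were the globin gene hbba2 (5.44 ± 0.41), the FGF receptor fgfr1a (5.06 ± 0.26, adjusted p = 2.73e-13), the BMP antagonist grem1a (4.37 ± 0.27, with -0.25 at its other probe), sox1b (at least 7.61-fold), the endoplasmic reticulum chaperone hspa5 (3.21 ± 0.34) and the growth arrest gene btg2 (3.4 ± 0.35). In all, 5306 genes passed, 2291 higher and 3015 lower, 2790 of them at least 2-fold, and 3187 genes when only these groups were fitted. Cycloheximide control 1 stood apart from controls 2 and 3, and without it hbba2 differed by 4.62, less than fgfr1a (4.98), and noto by -3.29.

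Mesendoderm genes gave 16 lower of 21 (camera adjusted p = 4.75e-07) and yolk syncytial layer genes 7 of 7 (adjusted p = 0.000392), both held with an estimated correlation. Enveloping layer genes gave 12 lower of 15 (adjusted p = 2.76e-06, and adjusted p = 0.0533 with an estimated correlation), organizer genes 10 of 13 (adjusted p = 0.000151, and adjusted p = 0.0533 with an estimated correlation) and first zygotic genes 15 of 24 (adjusted p = 0.000413, and adjusted p = 0.0501 with an estimated correlation). These 5 counts were the same adjusted over the list alone, and 0 members of these lists were higher by limma. Other lists moved both ways and did not pass: heat shock and unfolded protein genes with 7 higher and 7 lower of 20 (adjusted p = 0.805, median -0.07 and mean -0.03 with an upward test direction), later tissue markers with 2 higher and 4 lower of 9 (adjusted p = 0.556), ribosome biogenesis genes with 3 higher and 11 lower of 25 (adjusted p = 0.556), and germ plasm genes with 3 higher and 2 lower of 12 (adjusted p = 0.556). These counts were the same adjusted over the list alone. Ribosomal protein genes did not pass either, with 16 each way of 63 (17 higher and 16 lower adjusted over the list alone, adjusted p = 0.544). The cell cycle list gave 9 higher and 5 lower of 25 (the same adjusted over the list alone, adjusted p = 0.316), upward in camera and downward in fry. Cycloheximide lay on slide 4 and its controls on slide 3, so drug and slide cannot be told apart. Scaled to the 75th percentile, 1125 genes were higher and 6088 lower, with a median of all genes of -1.09.

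Whether Klf4 acted differently in mutants and wild type was tested by an interaction. The keratins krt5 (2.5 ± 0.34, adjusted p = 2.64e-05) and krt97 (1.83 ± 0.24) and the ectoderm gene dlx3b (2.66 ± 0.22) responded more positively in mutants, and dusp5 (-2.19 ± 0.24) less. The response of cdx4 was also more positive (adjusted p = 3.66e-08) and those of cldn15a (adjusted p = 6.21e-09) and stat1b (adjusted p = 1.92e-08) less, each with a control group not well above background. Of 369 genes that differed, 161 were more positive and 208 less. The enveloping layer list was more positive (7 of 15 and 1 less, 10 and 2 adjusted over the list alone, camera adjusted p = 3.41e-09, and adjusted p = 0.0348 with an estimated correlation). This list started lower in uninjected mutants than in wild type (mean of -1.88), and its difference holds that low start. In controls krt5 lay at 9.35 in mutants and 12.51 in wild type, and krt97 at 9.04 and 12.43. With Klf4 krt5 lay at 12.86 and 13.52, and krt97 at 12.18 and 13.74. The BMP list (5 more positive and 1 less of 21, the same adjusted over the list alone, adjusted p = 5.24e-05, and adjusted p = 0.0567 with an estimated correlation) had a mean of 0.21 that was -0.03 scaled to the 75th percentile. The cell cycle list had 3 more positive of 25 (3 adjusted over the list alone, adjusted p = 0.0291, and adjusted p = 0.348 with an estimated correlation) and the ribosomal list 0 called of 63 by limma (0 adjusted over the list alone, adjusted p = 0.0113, and adjusted p = 0.51 with an estimated correlation). The count was 228 without mutant Klf4 sample 3, 245 without wild type control 1 and 215 when only these groups were fitted, and the split was 45 and 90 scaled to the 75th percentile.

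The responses to FoxD3 in mutants and wild type differed at the keratins krt97, krt99 and krt17, which lay near background with FoxD3 in both genotypes and had started lower in mutants. krt97 (adjusted p = 4.57e-08) lay at 12.43 ± 0.29 in wild type controls and 7.25 ± 0.23 with FoxD3, where 1 of 3 samples was well above background, and at 9.04 ± 0.42 and 7.13 ± 0.09 in mutants, where 0 of 3 were. krt99 (adjusted p = 4.17e-09), krt17 (adjusted p = 1.01e-09) and eve1 (adjusted p = 1.78e-05) also differed toward the mutants and were not well above background with FoxD3 in either genotype. These differences thus hold the higher start in wild type. gata5 differed toward the mutants (1.81 ± 0.45) and mos away from them (-1.73 ± 0.52). Both FoxD3 groups lay on slide 2, the wild type controls on slide 1 and the mutant controls on slide 3, so this interaction cannot be told apart from slide. Of 675 genes, 413 differed upward and 262 downward, with 176 in all when only these groups were fitted and 62 when scaled to the 75th percentile. The enveloping layer list gave 11 upward of 15 (11 adjusted over the list alone, camera adjusted p = 4.04e-27), the mesendoderm list 5 of 21 (10, adjusted p = 3.39e-05), the immediate early list 6 of 27 (10 upward and 1 downward, adjusted p = 0.00143), the FGF list 2 of 12 (5, adjusted p = 0.00242) and the Krueppel-like list 2 of 10 (2, adjusted p = 0.0173). Counts adjusted over the list alone are in brackets, and these calls held with an estimated correlation. The others did not hold. The first zygotic list gave 7 upward and 1 downward of 24 (9 and 2 adjusted over the list alone, adjusted p = 0.0074, and adjusted p = 0.117 with an estimated correlation). The BMP list gave 5 and 1 of 21 (7 and 1 adjusted over the list alone, adjusted p = 0.0074, and adjusted p = 0.135 with an estimated correlation). The cell cycle list gave 5 upward of 25 (7 adjusted over the list alone, adjusted p = 0.016), with a mean of 0.42 that was -0.04 scaled to the 75th percentile, and the p53 list 3 of 13 (3 adjusted over the list alone, adjusted p = 0.0204). In both adjusted p = 0.128 with an estimated correlation.

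The responses to Klf4 with and without cycloheximide differed in 225 genes, 112 upward and 113 downward under cycloheximide. casq1b (-3.38 ± 0.21, adjusted p = 1.54e-10), shox2 (-3.13 ± 0.27), ehd2b (-3.09 ± 0.22), irf1b (-2.88 ± 0.32) and dlx3b (-2.29 ± 0.26) differed downward under cycloheximide, as did nog3 (adjusted p = 3.74e-07), whose cycloheximide controls were not well above background. gsc (1.97 ± 0.31) and gata6 (1.86 ± 0.32) differed upward. Both were low in the cycloheximide controls before any effect of Klf4, gsc at 7.78 ± 0.31 against 12.23 ± 0.6 in controls without the drug and gata6 at 6.77 ± 0.06 against 8.97 ± 0.78, which leaves little room to fall under it. The enveloping layer list did not pass (2 downward of 15, 4 downward and 2 upward adjusted over the list alone, camera adjusted p = 0.236). krt97 differed (-1.46 ± 0.28, adjusted p = 0.00291), and its difference was 0.36 from Agilent's processed signals and 0.55 in the deposited value table. Upward lists were mesendoderm (3 of 21, 11 adjusted over the list alone, adjusted p = 3.88e-12), first zygotic (3 of 24, 8, adjusted p = 9.32e-10), organizer (1 of 13, 5, adjusted p = 5.8e-08), yolk syncytial layer (2 of 7, 4, adjusted p = 7.47e-07) and neuroectoderm (2 of 25, 6 upward and 1 downward, adjusted p = 5.03e-05). These held with an estimated correlation. With cycloheximide alone the mean log2 differences of these lists were already -1.8, -1.43, -1.68 and -2.55 for the first 4, in the same order, so their upward differences hold this low start, and -0.51 for the neuroectoderm list, which did not pass there (adjusted p = 0.289). The immediate early (2 of 27, 2, adjusted p = 0.0337, and adjusted p = 0.159 with an estimated correlation) and ribosomal lists (0 of 63 by limma, 0, adjusted p = 0.000442, and adjusted p = 0.366 with an estimated correlation) did not. The count was 94 without cycloheximide control 2, 61 without cycloheximide Klf4 sample 2 and 100 when only these groups were fitted, and the split was 48 and 26 scaled to the 75th percentile.

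The responses to FoxD3 differed in 56 genes, 46 upward and 10 downward under cycloheximide. krt4 (3.35 ± 0.58), apoeb (4.1 ± 0.8) and mapk12b (3.18 ± 0.49) differed upward. So did krt92 (adjusted p = 4.59e-05), krt97 (adjusted p = 0.00133), afp4 (adjusted p = 0.00271) and gata6 (adjusted p = 0.00121), and osgn1 differed downward (adjusted p = 8.04e-07), each with a group not well above background. In the cycloheximide controls afp4 lay at 6.73 ± 0.06 (0 of 3 samples well above background) and apoeb at 6.63 ± 0.11 (1 of 3), so FoxD3 had little left to lower under the drug. With FoxD3 under the drug afp4 lay at 9.32 ± 0.8 and apoeb at 7.69 ± 0.43, so their differences also hold a rise. Neither rise was called over all genes in the comparison under the drug. Cycloheximide alone had also lowered the enveloping layer, yolk syncytial layer and mesendoderm lists (means of -1.98, -2.55 and -1.8). With FoxD3 the enveloping layer list had a mean difference of 0.62 under the drug and -0.75 without it. Its upward difference thus holds both a rise under the drug and a fall without it. krt97 lay at 7.01 ± 0.16 in the cycloheximide controls and 7.2 ± 0.16 with FoxD3. Enveloping layer (5 of 15, 9 adjusted over the list alone, camera adjusted p = 3.1e-18), yolk syncytial layer (4 of 7, 6, adjusted p = 1.15e-15) and mesendoderm genes (4 of 21, 6 upward and 1 downward, adjusted p = 5.25e-06) were upward and immediate early genes downward (0 of 27 by limma, 6 downward and 1 upward, adjusted p = 1.21e-07), and all 4 held with an estimated correlation. The count was 123 without mutant control 3, 104 and 31 without cycloheximide controls 1 and 2, 146 and 36 without mutant FoxD3 samples 1 and 2, 11 with only the FoxD3 sample of slide 4, 31 when only these groups were fitted and 24 when scaled to the 75th percentile.

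The 3 injections in mutants were compared with the same 3 controls, so their changes share chance values. Klf4 and Nanog-like had 288 genes higher and 108 lower in common, where independent lists give 82.2 and 31.1. Klf4 and FoxD3 had 61 and 112 (15.2 and 13.4), and FoxD3 and Nanog-like 111 and 71 (21.9 and 12.1). Among the shared lower genes of Klf4 and FoxD3 were gsc and gata6. The r across genes was 0.31, 0.31 and 0.4, where simulated unchanged groups against shared controls gave 0.32, 0.35 and 0.47. The covariances were 0.0866, 0.0621 and 0.121, where the simulations gave 0.0188, 0.0188 and 0.0403. Under cycloheximide Klf4 and FoxD3 shared 1 higher gene, krt4, where independent lists give 0.0111. Their r was -0.15 where the simulation gave 0.35, with a covariance of -0.00525 where it gave 0.025. With 3 controls these could not be split, so part of each excess may come from the shared controls. An effect of injection itself, common to these groups, cannot be told apart either. The FoxD3 samples and Nanog-like samples 1 and 2 lay on slide 2 and the controls on slide 3. A difference between slides may thus also be part of the overlap of FoxD3 and Nanog-like.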

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

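All tests of explanations and all counts of other splits in this part were chosen only after the results were seen. The responses to an injection differed between genotypes or with cycloheximide, by a test of the interaction, in 369 genes for Klf4 by genotype, 675 for FoxD3 by genotype, 225 for Klf4 by cycloheximide and 56 for FoxD3 by cycloheximide. Groups of 3 are too small for a test of single samples that stand apart.

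Klf4 by genotype gave log2 differences of 2.66 for dlx3b, 2.5 for krt5, 1.83 for krt97 and -2.19 for dusp5. FoxD3 by genotype gave 1.81 for gata5 and -1.73 for mos. Klf4 by cycloheximide gave -3.38 for casq1b, -3.13 for shox2, -3.09 for ehd2b, -2.88 for irf1b, -2.29 for dlx3b, -1.46 for krt97, 1.97 for gsc and 1.86 for gata6. FoxD3 by cycloheximide gave 4.1 for apoeb, 3.35 for krt4 and 3.18 for mapk12b. Where a group was not well above background no size is given, only limma's adjusted p. These were 3.66e-08 for cdx4 (upward), 6.21e-09 for cldn15a and 1.92e-08 for stat1b (downward) in Klf4 by genotype, and 4.57e-08 for krt97, 4.17e-09 for krt99, 1.01e-09 for krt17 and 1.78e-05 for eve1 (upward) in FoxD3 by genotype. They were 3.74e-07 for nog3 (downward) in Klf4 by cycloheximide, and 4.59e-05 for krt92, 0.00133 for krt97, 0.00271 for afp4, 0.00121 for gata6 (upward) and 8.04e-07 for osgn1 (downward) in FoxD3 by cycloheximide.

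The counts of called genes were set against other splits of the same samples. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other 9 were 1763 and 11 for uninjected genotypes, 2474 and 171 for FoxD3-injected genotypes, 885 and 33 for Klf4 in wild type, 1397 and 97 for Klf4 in mutants, 2108 and 2 for FoxD3 in wild type, 446 and 314 for FoxD3 in mutants, 1681 and 581 for Nanog-like and 5306 and 81 for cycloheximide, so that 1 of the 10 splits, the real one, was as large in each. Where the numbers pair the samples, the highest other split that parted all pairs gave 122 for FoxD3-injected genotypes, 4 for Klf4 in wild type and 7 for Klf4 in mutants. For FoxD3 under cycloheximide 2 of 10 splits were as large, with 25 genes against the real 22 when control 1 stood with FoxD3 samples 2 and 3. Of 100 splits of the interactions, 8 were as large for Klf4 by genotype (369 against a highest of 1777), 8 for FoxD3 by genotype (675 against 1848) and 6 for FoxD3 by cycloheximide (56 against 179), so chance was not excluded by this test. The highest counts, several times the real ones, came from splits in which at least 1 arm stood as labelled or turned whole, with the other arm mixed in 2 of the 3 cases, so they hold that arm's own response, a structure of the samples. Klf4 under cycloheximide, with 2 samples after averaging, was not split.

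The keratins krt4, krt5 and krt97 were higher with Klf4 under cycloheximide, and a dye effect is argued against, since within each dye the lowest Klf4 sample lay at least 0.98 log2 above the highest control. RNA carried over from Klf4 embryos without the drug stays open: the keratins reached 3.92 to 5.32% of their rise without it, and at that share the 14 genes suited to the test would rise by a median of 0.77, where they rose by 0.35 (quartiles 0.13 and 1.49), with 9 below the prediction and 5 not. The test decides nothing, as 3 of these 5 were the keratins, which set the share, and its first run without the 3 keratins, on 11 genes (predicted 0.74, observed 0.26, 75th percentile 0.55), would alone have argued against carry-over but left out called genes and is not relied on. Binding of the injected RNA to the keratin probes also stays open: the keratin excess differed 4.48-fold between Klf4 samples, where that of one unnamed probe that rose with Klf4 differed 1.08-fold and another lay at 9.59 to 9.63 (n = 2 after averaging, group means 6.62 to 7.02 without Klf4 and 9.02 to 9.61 with it), but whether either reads that RNA is not known. A response that needs no new protein may explain the keratins as a hypothesis, which cannot be told apart from these.

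Of the genes called for FoxD3 under cycloheximide 15 were higher. Among them were krt92, which fell with FoxD3 without the drug, and krt4, whose difference of -1.33 there did not pass (adjusted p = 0.0687). Carry-over from FoxD3 embryos is argued against: 53 genes bright in those embryos and dim in the cycloheximide controls would rise by a median of 1.17, and rose by 0 (75th percentile 0.16, 52 of 53 below the prediction). The slides stay open, because FoxD3 samples 2 and 3 lay on slides of their own. The sample on the slide of the controls had a median difference of 0.73 over these genes (1.02 over all samples) and lay above all controls in 15 of 15, but it is 1 sample, and blocked for slide 1 gene passed. An effect of FoxD3 may be the source and is untested apart from the slide.

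Cycloheximide control 1 stood apart from controls 2 and 3 at 697 probes over 2-fold, 450 higher and 247 lower, and without it FoxD3 under cycloheximide called 157 genes in place of 22, in 134 of which control 1 lay nearer the FoxD3 samples. A swap with a Klf4 sample is argued against, as the unnamed probe that Klf4 raised most lay at 8.31 in control 1 and at 13.7 or more in the Klf4 samples. A swap with a FoxD3 sample is not decided. Control 1 differed from the nearest FoxD3 sample at 109 probes, where FoxD3 samples differed from each other at up to 27. Compared singly, it differed from controls 2 and 3 at 727 and 706 probes. Its array was the dimmest under cycloheximide, which may itself add probes over 2-fold, so these counts cannot settle it. Whether its dim array was the whole cause is not decided. Its deviation correlated across genes with that of the FoxD3 samples, at r of 0.77 and 0.81 against controls 2 and 3. Genes are not independent replicates, and controls 2 and 3 differed at 0 probes over 2-fold, so these correlations are not separate tests. Of the samples under cycloheximide, FoxD3 samples 2 and 3 were the next dimmest. Their median spot signals were 144 and 179.5, with 106 in control 1 and at least 215 in the others. Klf4 samples 1 and 3 lay with control 1 at some genes, such as cyth1a (9.61 and 9.52, and 9.49 in control 1, against 6.71, 6.7 and 6.76 in controls 2 and 3 and Klf4 sample 2). The FoxD3 samples lay there too (9.74, 9.51 and 9.64). Across genes the r between the deviation of control 1 and that of Klf4 samples 1 and 3 was 0.19, with the same sign at 427 of the 697 probes. It was -0.16 scaled to the 75th percentile and -0.03 after loess and Aquantile, and controls and Klf4 samples share arrays. A difference in embryo batch may remain, with no label to test it, and no biological explanation was tested.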

How the results depend on the processing

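Of 368 values of counts and overlaps under alternatives, 245 stayed within 1.5 times the main value or on the same side of the threshold. Of 2050 list values 1880 kept direction and side and 170 lost the call, and of 3894 values of named genes 3589 kept both, 291 lost the call, 12 gained one and 2 reversed: krt97 in Klf4 by cycloheximide, -1.46, was 0.36 from Agilent's processed signals and 0.55 in the deposited value table. The lost calls of named genes fell unevenly. They were 56 of 150 values for FoxD3 under cycloheximide and 15 of 67 for Klf4 under cycloheximide, but 0 of 285 for cycloheximide itself. The cause of these changes was not tested, except that stricter filters test fewer genes and smaller fits hold fewer samples. Signal over background limits dim genes: 5230 of 12951 kept probes were well above background in all samples.

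Counts that moved by over 1.5 times follow. Processed signals gave 40 for FoxD3 under cycloheximide and 223 for Klf4 by genotype. The 75th percentile gave 487 for uninjected genotypes, 689 for FoxD3-injected genotypes, 230 for Klf4 in wild type, 15 for Klf4 under cycloheximide, 237 for FoxD3 in wild type, 20 for FoxD3 in mutants, 51 for FoxD3 under cycloheximide, 217 for Nanog-like, and for the interactions 135 (Klf4 by genotype), 62 (FoxD3 by genotype), 74 (Klf4 by cycloheximide) and 24 (FoxD3 by cycloheximide). Loess and Aquantile gave 1110 for FoxD3-injected genotypes, 546 for Klf4 in wild type, 39 for Klf4 under cycloheximide and 257 for FoxD3 in mutants. The deposited value table gave 551 for Klf4 in wild type, 581 for Nanog-like, and 179, 284 and 85 for the first 3 interactions. With no filter on dim probes, Klf4 in mutants gave 875 and Klf4 by cycloheximide 146. With probes well above background in all samples, the 10 comparisons gave 488 and 1093 (genotypes), 368, 809 and 1 (Klf4 in wild type, mutants and under cycloheximide), 889, 144 and 0 (FoxD3, by limma), 867 (Nanog-like) and 2460 (cycloheximide), and the interactions 110, 122, 40 and 2.

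No array block gave 1053 for FoxD3-injected genotypes, 375, 409 and 4 for Klf4 in wild type, mutants and under cycloheximide, and 104, 356 and 82 for the first 3 interactions. Slide as a random block gave 1067, 379, 434 and 4 for the same comparisons, 244 for FoxD3 in mutants and 104, 293 and 86. Slide as a fixed block gave 680 for FoxD3 in mutants, 1 for FoxD3 under cycloheximide, 291 for Nanog-like and 171 for FoxD3 by cycloheximide, and could not be fitted for uninjected genotypes, FoxD3 in wild type, cycloheximide and FoxD3 by genotype. The replicate block gave 14 for Klf4 under cycloheximide, with the averaged pair as 2 samples, and changed no other count by over 1.5 times; without the block that pair as 2 samples gave 15. eBayes with neither trend nor robust gave 14 for FoxD3 under cycloheximide. Only the groups of a comparison gave 542 and 1491 (uninjected and FoxD3-injected genotypes), 2396, 303 and 2 (Klf4 in wild type, mutants and under cycloheximide), 9 (FoxD3 in mutants), 0 (FoxD3 under cycloheximide, by limma), 13 (Nanog-like) and 3187 (cycloheximide), and 215, 176, 100 and 31 for the interactions. Chosen after seeing the data were Nanog-like sample 3 alone (370), FoxD3 under cycloheximide with the slide 4 sample alone (0, and 11 in its interaction) and Klf4 by cycloheximide with Klf4 sample 2 alone (141).

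Leaving out each sample gave 1256 to 2053 for uninjected genotypes, 1723 to 2292 for FoxD3-injected genotypes, 520 to 734 for Klf4 in wild type, 808 to 1558 in mutants and 2 to 11 under cycloheximide, 1571 to 1949 for FoxD3 in wild type, 238 to 813 in mutants and 3 to 157 under cycloheximide, 1032 to 2880 for Nanog-like, 4563 to 5410 for cycloheximide, and 228 to 527, 467 to 975, 61 to 323 and 31 to 146 for the interactions. The number of lists called with an estimated correlation was 5 for uninjected and 1 for FoxD3-injected genotypes, 2 for Klf4 under cycloheximide, 3 and 1 for FoxD3 in mutants and under cycloheximide, 0 for Nanog-like, 2 for cycloheximide, and 1 and 5 for Klf4 and FoxD3 by genotype. With fry it was 10 for FoxD3-injected genotypes, 1 and 2 for Klf4 and FoxD3 under cycloheximide, 15 for FoxD3 in wild type, 15 for cycloheximide and 2 for Klf4 by genotype. The Klf4 overlaps at 2-fold were 54 higher and 54 lower. With uninjected genotypes in place of FoxD3-injected ones, 75 genes were higher in mutants and higher with Klf4, no longer past the threshold, and these comparisons share the mutant controls. With Klf4 under cycloheximide, which shares no samples with the uninjected genotypes, 6 genes were lower in mutants and higher with Klf4, now past it (adjusted p = 2.11e-05).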

Other observations

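The genes and overlaps in this part were chosen after their values were seen. casq1b and tnni2a.3, known from muscle, and dcn, a proteoglycan gene, rose with Klf4 in both genotypes. The fixed list of later tissue markers, which holds other muscle genes, gave 0 called of 9 by limma in wild type (camera adjusted p = 0.941) and 0 higher and 2 lower of 9 in mutants (adjusted p = 0.589). casq1b lay at 10.38 ± 0.2 in wild type and 10.6 ± 0.09 in mutants with Klf4, and at 6.92 ± 0.44 and 7.09 ± 0.13 in the controls (log2 signal, SD, n = 3), of which 0 of 3 and 1 of 3 were well above background. tnni2a.3 lay at 10.34 ± 0.26 and 9.77 ± 0.16 with Klf4, where the controls had 7.68 ± 0.05 and 7.24 ± 0.31, and dcn at 10.73 ± 0.2 and 9.76 ± 0.28, where the controls had 8.02 ± 0.15 and 7.72 ± 0.35. Under cycloheximide with Klf4 they lay at 6.96, 6.7 and 7.16, beside 6.81, 6.61 and 7.16 in the cycloheximide controls.

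One unnamed probe, A_15_P119004, lay at 15.34 ± 0.18 and 15.12 ± 0.21 in mutants and wild type with Klf4, at 10.34 ± 0.49 and 11.41 ± 0.14 in their controls, and under cycloheximide at 13.76 ± 0.07 with Klf4 (n = 2), 7.99 ± 0.29 in controls and 6.72 ± 0.08 with FoxD3. It is not named here, and whether it reads the injected RNA is not known.

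Genes lower in FoxD3-injected mutants than in FoxD3-injected wild type and lower with Klf4 in wild type, comparisons that share no samples, numbered 91, where independent lists give 48.8 (Fisher's exact test, adjusted p = 3.68e-09). cdx4, zic2b and vox were among them. Genes lower in those mutants and higher with Klf4 numbered 77, where independent lists give 48.2 (adjusted p = 4.23e-05), and r across all genes was -0.03, so the excess went both ways.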
